A study of Mus musculus with 2 samples.

How the data were processed

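Polyadenylated RNA was profiled by sequencing in 2 samples of mouse embryonic stem cells in which Ago1 had been knocked out. Per the labels, the cells were E14 cells of 129/Ola background, grown in serum with leukaemia inhibitory factor (LIF) on gelatin. E14 is a male line derived from blastocysts. RNA was taken up in Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols, and the labels describe the protocol as reverse-stranded. The labels give 1 group, Ago1 KO, with replicates 1 and 2, called KO1 and KO2 here. They do not say whether these came from separate clones or separate cultures, so the spread between them may be technical. No control library was used here.

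The authors deposited 1 table of whole-number read counts per gene, not normalized. The build was GRCm38, per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. The table held 55421 Ensembl gene identifiers, of which 55240 were found in GENCODE release M21 of the GRCm38 annotation. The other 181 held 0.00416% of the counts. Both libraries had a count of 0 at 25803 genes. Total counts were 57048330 in KO1 and 54408708 in KO2. With 3 counts taken as the upper limit that a count of 0 allows, the floor was 0.0528 counts per 1000000 (CPM) in KO1 and 0.0549 CPM in KO2. All intervals and floors cover counting error only, since reads made by PCR are not independent molecules.

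Whether the counting had kept the strands apart was checked on protein-coding genes with at least 50% of their exons under another gene. With the overlap on the same strand, 324 genes had a median of 0 counts per kb. With the overlap on the opposite strand, 189 genes had a median of 36.4 counts per kb, beside 53.4 for 16622 genes with no overlap. Ago1 had 0% of its exons under another gene on either strand. Genes with near-identical copies, such as Zscan4c and Zscan4d, ribosomal protein pseudogenes and many of the predicted Gm genes, are uncertain, because how shared reads were counted is not given in the sources used here.

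Counts were scaled to CPM with edgeR 4.0.16 in R 4.3.3, using trimmed mean of M values (TMM) factors, which were 0.996 for KO1 and 1.00 for KO2. A gene was called detected at a CPM of at least 1 in both libraries. Levels are given as mean ± SD over 2 libraries. The spread between the libraries was taken as the common biological coefficient of variation of edgeR with an intercept-only design. With 1 group there was no second group to test against, so no quasi-likelihood test was made and no p-value across genes is given. Gene names, positions, exonic lengths and GC content of the longest transcript came from GENCODE release M21. Interval overlaps were made with bedtools 2.31.1, and all other steps with python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

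The libraries were compared gene by gene as the ratio of TMM-scaled counts, KO2 over KO1, with an exact conditional binomial 95% interval and a prior count of 0.5 on the log2 value. A gene was counted as differing when its whole interval lay beyond 2-fold and its summed count was at least 50. This is a rule of size that compares 2 libraries, not conditions. It has no replicate check. For 29 gene lists holding 355 genes, of which 353 were in the table, the median log2 ratio of members with a mean of at least 10 counts was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The level of each list, as the median log2(CPM + 1), was placed among 10000 random lists of genes with a count. The 22 chromosomes, the mitochondrial one included, were treated like the lists with genes at a mean of at least 50 counts. For chromosomes with more than 100 such genes, 1000 random sets were drawn in place of the 10000 planned.

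Design, lists and the rule for naming genes were fixed before the data were examined. The rule took the 4 Argonaute genes, the 2 highest and 2 lowest members of each list described, a fixed set of regulators, the 10 most abundant genes, and the 10 genes highest and 10 lowest in KO2 among those counted as differing, ranked by the nearer bound. Some genes that the rule takes are not reported here. Genes outside it are marked as chosen after their values were seen. A loess correction of the log2 ratio for transcript GC content, with a span of 0.3, was added after seeing the data. Other alternatives were library size without TMM, DESeq2 1.42.0 size factors and dispersion, other count and fold thresholds, each library alone, scaling to exonic length, and leaving out mitochondrial or noncoding genes.

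The steps were tested on simulated data. With counts drawn for 13347 genes at coefficients of variation of 0.05, 0.1 and 0.2, edgeR gave 0.0505, 0.0983 and 0.199. With counting noise only, the ratio rule recovered 89% of 200 genes changed by 3-fold among 15620 genes and called 0 unchanged genes. The real libraries differed by more than counting noise, so this does not give the rate of such calls in them.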

Results

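The mRNA of Ago1 knockout E14 mouse embryonic stem (ES) cells was profiled in 2 libraries, KO1 and KO2, of 57048330 and 54408708 counts. The design gives 1 group in duplicate, so the data describe which genes the knockout cells transcribed and how far the duplicates differed. At a CPM of at least 1, 13347 genes were detected in both libraries, 12148 of them protein coding. The most abundant transcripts were mt-Co1, a mitochondrial subunit of cytochrome c oxidase, at 12029 ± 1476 CPM (SD, n = 2), and Eef1a1, a translation elongation factor, at 9458 ± 76.7 CPM. They were followed by the chaperone genes Hsp90ab1 and Hsp90aa1, then mt-Nd1, Npm1, mt-Cytb, Ncl, Pabpc1 and Hspa8, the last at 3541 ± 125 CPM. The 10 most abundant genes of each library held 5.90% of the counts in KO1 and 5.31% in KO2. Mitochondrially encoded genes held 3.03% and 2.5%.

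Ago1, the targeted gene, encodes an Argonaute protein that binds small RNAs. Reads of Ago1 were present in both libraries, with 1497 counts in KO1 and 452 in KO2. These were 26.4 CPM (95% exact Poisson interval 25.03 to 27.7) in KO1 and 8.27 CPM (7.53 to 9.07) in KO2, with a mean of 17.3 ± 12.8 CPM (SD, n = 2). Ago1 was 3.18-fold higher in KO1 than in KO2 (95% interval 2.87 to 3.55). The gene (ENSMUSG00000041530) lies on chromosome 4 from 126435012 to 126468583 on the minus strand of GRCm38. Counts per gene do not show where in the transcript the reads lay, and no wild-type level was used here. The remaining reads therefore neither show nor exclude the mutation.

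Among the other Argonaute genes, Ago2, the member with slicer activity, was the most abundant at 502 ± 1.69 CPM (SD, n = 2), with 500 CPM in KO1 and 503 CPM in KO2. Ago3 was at 36.2 ± 7.5 CPM, and Ago4 was below the detection threshold at 0.580 ± 0.20 CPM. Ago2 made up 90.3% ± 3.36 of the Argonaute CPM, and 89.1% ± 4.6 after scaling to exonic length. Ago2 (ENSMUSG00000036698) lies on chromosome 15, whereas Ago3 (ENSMUSG00000028842, 126331704 to 126429556) and Ago4 (ENSMUSG00000042500, 126489541 to 126533472) flank Ago1 on chromosome 4.

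**Figure D1:**
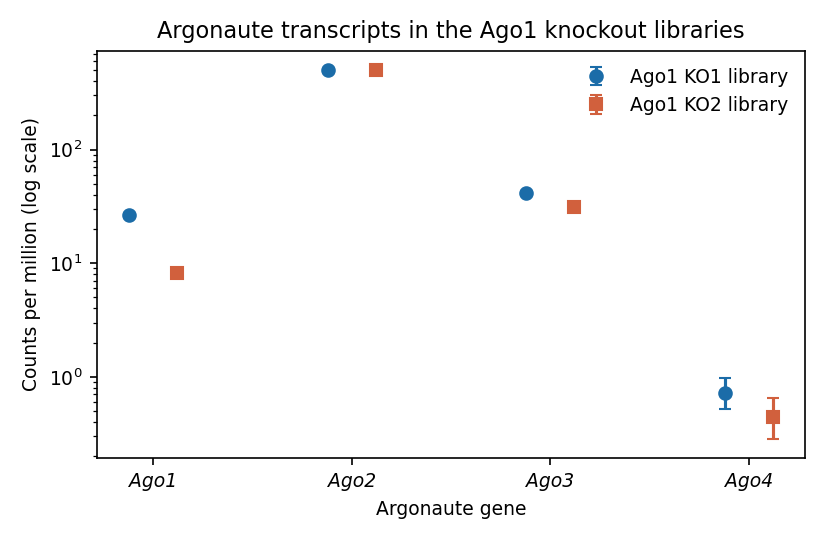
CPM of the 4 Argonaute genes on a log axis in KO1 (circles) and KO2 (squares), with exact 95% Poisson intervals, which are smaller than the symbols except for Ago4. Ago2 lies at 500 and 503 CPM, and Ago1 at 26.4 and 8.27 CPM.

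The microRNA and RNA interference genes were expressed throughout, with 24 of 24 detected. Drosha and Dgcr8, which form the nuclear Microprocessor, were at 376 ± 7.17 and 84.3 ± 8.69 CPM (SD, n = 2). Dicer1, which cuts precursors to mature microRNAs, was at 185 ± 9.07 CPM, and Tnrc6a, an Argonaute partner in silencing, at 107 ± 3.0 CPM. The lowest members were Lin28b at 36.5 ± 6.78 CPM and Prkra at 9.44 ± 1.44 CPM. Of 10 listed targets of ES-cell microRNAs, 10 were detected. Cdkn1a, encoding the inhibitor p21, was at 45.2 ± 6.50 CPM, the retinoblastoma relative Rbl2 at 13.8 ± 0.621 CPM and the Hippo kinase gene Lats2 at 3.35 ± 0.415 CPM. Ei24 was the highest at 163 ± 14.9 CPM, and Dkk1 and Tgfbr2 the lowest at 2.71 ± 0.468 and 1.28 ± 0.00262 CPM.

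Pluripotency genes were among the well expressed groups, with 15 of 15 general and 15 of 15 naive markers detected. The core factors Pou5f1, Nanog and Sox2 were at 976 ± 275, 619 ± 40.7 and 309 ± 16.9 CPM (SD, n = 2). The naive factors Zfp42, Esrrb and Klf4 were at 719 ± 5.10, 671 ± 86.7 and 175 ± 13.5 CPM. Trim28 at 1799 ± 403 CPM and L1td1 at 1183 ± 98.4 CPM led the general list, and Dppa5a at 1595 ± 119 CPM the naive list. Gdf3 and Zfp296 were lowest in the first, at 67.8 ± 7.65 and 41.8 ± 21.7 CPM, and Prdm14 and Dppa3 in the second, at 22.03 ± 1.21 and 2.45 ± 0.258 CPM. Both list medians lay above 100% of random lists of genes with a count. So did those of the microRNA pathway, heterochromatin, Polycomb, cell cycle, p53 response, glycolysis and housekeeping lists, so this rank is not particular to pluripotency genes.

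Primed epiblast markers were mixed, with 10 of 13 detected. The DNA methyltransferase genes Dnmt3b and Dnmt3a were at 241 ± 27.5 and 163 ± 23.7 CPM, and Otx2, a regulator of formative cells, at 14.8 ± 0.599 CPM. Fgf5 and Fgf8 lay at 0.289 ± 0.109 and 0.0722 ± 0.0274 CPM. Of the two-cell-like genes, 4 of 11 in the table were detected, with Zscan4c at 2.09 ± 0.387 CPM and Zscan4d at 1.99 ± 0.541 CPM. Gm4340 had 0 counts in KO1 and 2 in KO2, and Tcstv1 had 0 in both.

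Lineage markers were detected in part. For ectoderm and neural genes 6 of 12 were detected, for mesoderm 4 of 12, for definitive endoderm 4 of 10 and for trophectoderm 6 of 12. Gbx2 at 68.2 ± 6.84 CPM and Tubb3 at 34.3 ± 15.4 CPM led the ectoderm list, in which Neurog2 and Dcx had 1 count each over both libraries. Pdgfra at 13.8 ± 0.230 CPM and Eomes at 5.58 ± 0.421 CPM led the mesoderm list, with Tbx1 and Gsc at 0.0451 ± 0.0139 and 0.0268 ± 0.0120 CPM. Gata6 at 9.96 ± 0.389 CPM and Sox7 at 7.30 ± 0.988 CPM led the definitive endoderm list, in which Cer1 had 1 count and Afp 0. Tfap2c at 31.8 ± 4.86 CPM and Krt8 at 17.8 ± 5.15 CPM led the trophectoderm list, with Elf5 and Plac1 at 0.0796 ± 0.0866 and 0.0359 ± 0.000992 CPM. The lineages are list names fixed beforehand, and the detected members do not by themselves show cells of those lineages.

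Primitive endoderm genes were detected in 12 of 12 cases, from the laminin genes Lamb1 and Lama1 at 155 ± 20.7 and 135 ± 21.6 CPM down to Sox17 and Amn at 2.70 ± 0.633 and 2.06 ± 1.20 CPM. Of 14 fibroblast genes, listed because feeder cells can accompany ES cells, 5 were detected. Fn1 and Vim, which ES cells also express, were at 853 ± 65.4 and 138 ± 16.2 CPM. Lum and Postn had 0 counts in both libraries.

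**Figure D2:**
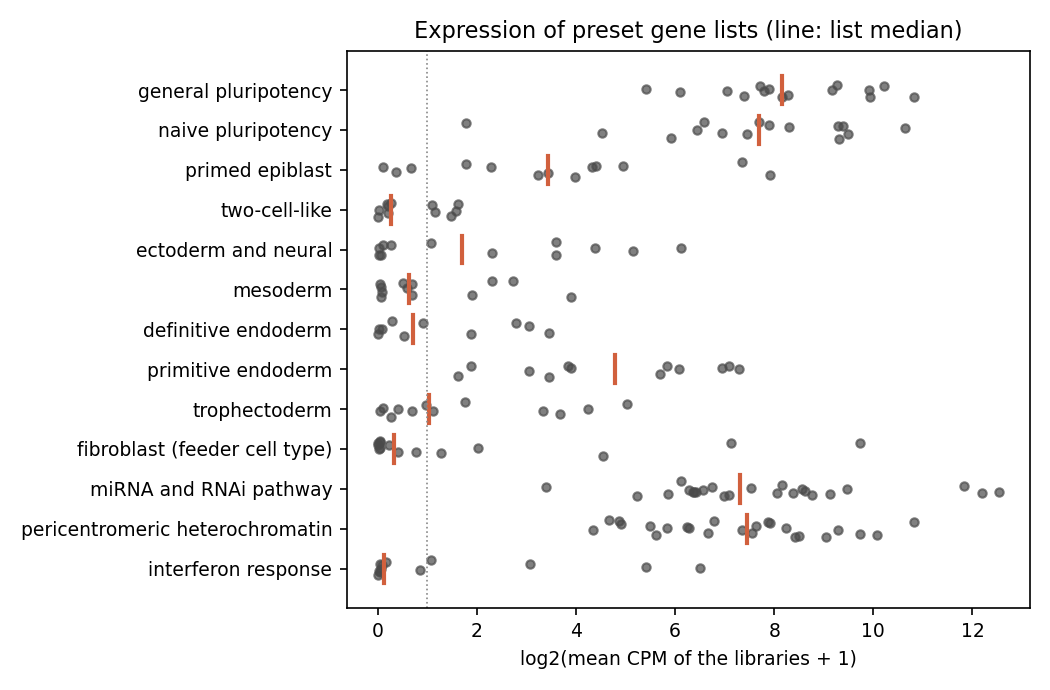
Mean expression of each member (points) of 13 gene lists as log2(CPM + 1), with the list median (vertical line) and a dotted line at a CPM of 1. All general and naive pluripotency genes lie to the right of the dotted line, as do the 24 microRNA pathway genes.

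Genes of pericentromeric heterochromatin were expressed in 24 of 24 cases. The HP1 genes Cbx5, Cbx1 and Cbx3 were at 1077 ± 188, 300 ± 34.1 and 109 ± 12.6 CPM (SD, n = 2). The H3K9 methyltransferase genes Setdb1, Suv39h2 and Suv39h1 were at 235 ± 13.2, 43.9 ± 9.28 and 19.2 ± 0.118 CPM, and Setdb2 at 24.5 ± 3.68 CPM. All 13 Polycomb genes were detected, from Jarid2 at 887 ± 32.1 CPM and Rbbp4 at 663 ± 84.8 CPM down to Ezh1 at 35.7 ± 0.365 CPM and Ring1 at 3.93 ± 1.17 CPM.

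Cell cycle and signalling genes were detected in full, with 20 of 20 cell cycle, 14 of 14 p53 response, 11 of 11 LIF and STAT3, 11 of 11 ERK and FGF feedback and 8 of 8 BMP and SMAD genes. Top2a was at 1033 ± 176 CPM and Mcm3 at 640.2 ± 57.8 CPM, with E2f1 and Ccne2 lowest of the cell cycle list at 36.0 ± 8.87 and 32.3 ± 6.85 CPM. Trp53, encoding p53, was at 349 ± 84.1 CPM and its target Trp53inp1 at 356 ± 96.9 CPM, while Phlda3 and Bbc3 were at 18.2 ± 3.52 and 11.8 ± 6.18 CPM. Tfcp2l1 and Lifr, at 634 ± 59.2 and 196 ± 25.8 CPM, led the LIF list, which ended in Pim1 at 57.6 ± 8.06 CPM and Junb at 9.14 ± 7.80 CPM. Etv5 and Spry4, at 521 ± 34.9 and 336 ± 7.78 CPM, led the ERK list, and Ier3 and Fos were its lowest at 5.23 ± 1.20 and 4.74 ± 1.4 CPM. Smad7 and Id1, at 97.2 ± 12.3 and 32.3 ± 9.0 CPM, led the BMP list, with Smad6 and Msx2 at 2.33 ± 0.953 and 1.35 ± 0.291 CPM.

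The duplicates differed at 165 of 15619 genes by the 2-fold rule, with 153 higher and 12 lower in KO2. Ago1 was among the 12 lower genes, with a log2 ratio of -1.67 (95% interval -1.83 to -1.52). It had the second lowest ratio of the 12398 genes with a summed count of at least 200. The other lower genes included 7 genes of skeletal muscle at low counts, a grouping made after their values were seen. Tnnt3, a fast troponin gene, had 111 counts in KO1 and 11 in KO2. The actin gene Acta1 had 118 and 14, the calcium pump gene Atp2a1 113 and 16, and the myosin gene Myh4 74 and 16. Myl1 had 69 counts in KO1 and 0 in KO2. Ckm with 96 and 24 counts and Tnnc2 with 55 and 12 completed the muscle genes, and were named after their values were seen. The 5.8S ribosomal RNA gene n-R5-8s1 had 512 and 76 counts, and the small nuclear RNA genes Gm22513, Gm25360 and Gm22973 had 160 and 16, 89 and 8, and 60 and 2. The libraries were made from polyadenylated RNA, so these ribosomal and small nuclear RNA counts are not taken as levels of those RNAs.

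Among the 153 genes higher in KO2, Gm47283, annotated on the Y chromosome, ranked first at 9.54-fold, from 168 to 1545 counts. It was followed by the annotated microRNA gene Gm23935 at 5.35-fold and the ribosomal protein gene Rpl36 at 4.09-fold, from 4118 to 16187 counts. Polr2l, a subunit of RNA polymerases, was 4.23-fold higher and Cox16, a cytochrome oxidase assembly factor, 5.33-fold. Pcsk1n, Gm24187, the AP-1 gene Junb, Gm10073 and Gm26917 completed the first 10, at 5.17-, 6.59-, 4.04-, 4.47- and 3.50-fold. Reads at Gm23935 and Gm24187, both annotated as microRNA genes of 57 bases, are not taken as levels of mature microRNAs. Of the list members named by the rule, Zfp296 was 2.16-fold and the Y-linked Ddx3y 2.23-fold higher in KO2. Outside the rule, and chosen after their values were seen, Utf1 and Mbd3 were 2.95- and 2.28-fold higher, and the Y-linked genes Uty and Zfy1 3.41- and 2.68-fold.

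The log2 ratio rose with transcript GC content, with a Spearman correlation of 0.844 across 13932 genes, which are not independent replicates. Median GC content was 60.5% for the 153 genes higher in KO2 and 49.6% for all genes tested. After the GC correction, 42 genes differed, 26 higher and 16 lower in KO2, and 36 of the 165 were kept. All 12 genes lower before correction were kept, Ago1 at a log2 ratio of -1.73 (-1.88 to -1.57). Rn7sk, Gm9887, Gm8066 and Gm12905, named after their values were seen, joined the lower genes through the correction. Their uncorrected log2 ratios were -0.96, -0.20, 0.29 and 0.10, and the last 3 had a GC content from 71.4% to 75.5%. Of the first 10 higher genes 6 were kept, and Gm23935, Gm24187, Junb and Gm26917 were not. Utf1, Zfp296 and Mbd3 were not kept, whereas Gm47283, Uty, Zfy1 and Ddx3y were.

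**Figure D3:**
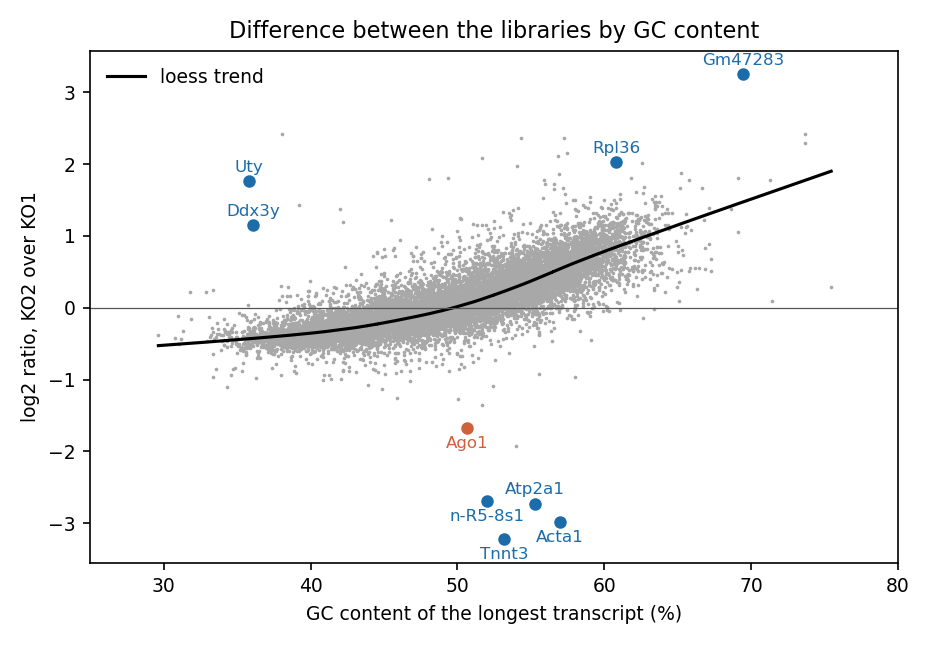
log2 ratio of KO2 over KO1 against GC content of the longest transcript (%) for genes with a summed count of at least 100 (grey points), with the loess trend used for the correction (line). Larger points mark Ago1 (orange) and genes named in the text (blue). The trend lies at -0.35 at 40% GC and 0.78 at 60% GC, and Ago1 lies at -1.67.

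Gene lists were compared between the duplicates by their median ratio. Without the GC correction, 6 of 29 list medians lay outside the central 95% of random lists, where 1.45 would be expected by chance. These were the Argonaute genes (median log2 ratio -0.56), two-cell-like (-0.39), trophectoderm (0.51), cell cycle (0.12), p53 response (0.35) and ERK and FGF feedback (0.33). With members at a mean of at least 50 counts, the trophectoderm median was 0.31 and lay inside. After the correction, 4 lay outside, the Argonaute genes (-0.35), BMP and SMAD targets (0.29), E14 sex-linked genes (0.32) and housekeeping genes (0.12). The p53 response median changed sign, to -0.02. The Argonaute median lies between Ago3 and Ago4, and without Ago4, under a mean of 50 counts, it was -0.11 and inside the range after correction. The general and naive pluripotency, microRNA pathway, heterochromatin and Polycomb lists lay inside the range both ways.

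By chromosome, 19 of 22 medians lay outside the range of random gene sets without the GC correction and 7 with it, on chromosomes 4, 7, 8, 13, 17, X and Y. The corrected medians of the autosomes and X ran from -0.05 to 0.03, and that of the 8 genes annotated on Y was 1.31. At Ago1, the 10 nearest genes with a mean of at least 50 counts had a corrected median of -0.08, and Ago3 was at -0.11 (95% interval -0.21 to -0.02). Ago4, under that minimum with 41 counts in KO1 and 24 in KO2, was at -0.59 (-1.40 to 0.15).

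**Figure D4:**
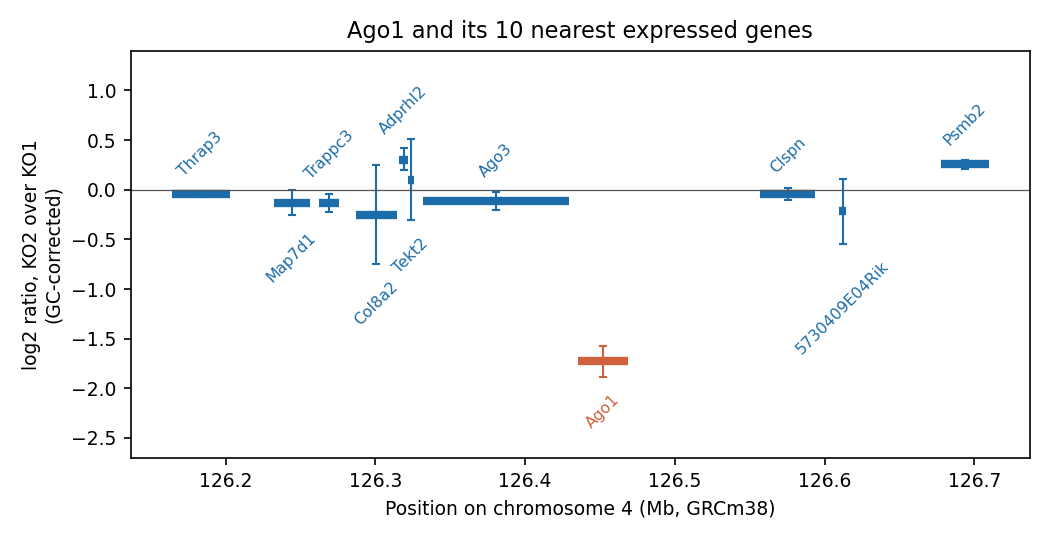
GC-corrected log2 ratio of KO2 over KO1 for Ago1 and its 10 nearest genes with a mean of at least 50 counts, drawn at their positions on chromosome 4 (Mb, GRCm38), with 95% counting intervals. Ago1 lies at -1.73, and the 10 neighbours have a median of -0.08.

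Across genes, log2(CPM + 1) of the libraries had a Pearson correlation of 0.995 and a Spearman correlation of 0.967 over 29618 genes, which are not independent replicates. The chi-square of their counts was 76.4 per degree of freedom over genes with at least 10 reads, so the files are not copies of 1 library. The common biological coefficient of variation was 0.193. It was estimated without the GC correction, so it includes the GC-related part of the difference and is not biological spread alone.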

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

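The GC corrections were chosen after seeing the data, and all other alternatives in this part before. No paired analysis was possible because the labels give 1 group only. With each library alone, Ago1 was at 8.27 CPM without KO1 and 26.4 CPM without KO2, against a mean of 17.3, so its level depends on the library. Each library alone gave an Ago2 share from 87.9% to 92.7%, detected genes from 13604 to 13732 and detected list members from 292 to 296. With only 2 libraries, each lies within 1 SD of their mean by construction, so this says nothing about stability. Under the other alternatives, the Ago1 level and the Ago2 share moved by less than 1 SD, the numbers of detected genes and list members by less than 1.5-fold, and the log2 ratio of Ago1 by less than its counting interval allows. The count of 165 differing genes was 1031 at 1.5-fold and 24 at 3-fold, which follow from the threshold, 42 with the GC correction and 27 with the correction and protein-coding genes only. The count of 12 lower genes was 32 at 1.5-fold, 21 with a summed count of at least 10, 21 with no filter and 2 with a summed count of at least 200. Since 10 of the 12 thus had fewer than 200 counts in all, depth limits what they show. The 6 lists outside the random range became 5 with members at a mean of at least 50 counts. With that minimum and the GC correction, the Argonaute list (-0.11) lay inside and the ectoderm list (-0.18) outside. The 19 chromosomes outside the random range became 7 with the GC correction, and the p53 response median reversed from 0.35 to -0.024. Only the GC correction changed that sign, and the corrected median lay inside the range of random lists, so no shift in the opposite direction is shown. Among other values of single lists, 16 moved lower and 6 higher under an alternative by more than their limit. With DESeq2, both size factors came out as 1, which left the libraries unscaled.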

Other observations

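Tests in this part were written after the uncorrected ratios had been seen. Those of length, lineage lists, Ago1 and its neighbours used GC-corrected ratios, and those of GC content and muscle genes uncorrected ones unless stated. The test of reads shared between Argonaute genes was written after its result was seen, and the muscle lists after the 7 muscle genes above, which they leave out, were noticed. The conditions on lineage list members going both ways and on muscle list members near the floor, the muscle ratios without Pvalb and Tnni2 or with GC correction, and the 10-count minimum for lists other than adult muscle were added after the results were seen.

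Other lists fixed beforehand described metabolism and silenced gene classes. All 12 glycolysis and hypoxia genes were detected, from Ldha and Eno1 at 1858 ± 164 and 1843 ± 459 CPM (SD, n = 2) to Vegfa and Egln3 at 47.3 ± 8.62 and 16.6 ± 2.03 CPM. All 12 cholesterol synthesis genes were detected, from Hmgcs1 at 284 ± 34.5 CPM to Idi1 and Fdps at 40.9 ± 10.8 and 6.68 ± 1.01 CPM. All 12 stress genes were detected, from Asns and Hspa5 at 660.0 ± 54.5 and 586 ± 58.7 CPM to Hspa1b and Hspa1a at 2.82 ± 0.230 and 1.43 ± 0.547 CPM. Imprinted genes were detected in 15 of 20 cases, with Peg10 and Rian at 474 ± 18.8 and 336 ± 44.6 CPM, Igf2 at 0.20 ± 0.183 CPM, and Rtl1 at 0 counts in KO1 and 3 in KO2. Germline genes were detected in 9 of 10 cases, led by Sycp3 at 44.6 ± 11.8 CPM and ending in Tex101 and Dpep3 at 1.10 ± 0.0556 and 0.493 ± 0.0498 CPM. The PIWI pathway had 8 of 10, led by Mael and Piwil2 at 39.5 ± 4.87 and 31.7 ± 0.913 CPM and ending in Tdrd9 and Asz1 at 0.938 ± 0.381 and 0.126 ± 0.00347 CPM. Interferon response genes were detected in 3 of 12 cases, with Ddx58 at 89.8 ± 6.12 CPM and Bst2 at 41.7 ± 10.7 CPM, while Isg15 had 0 and 2 counts and Ifih1 0 in both.

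All 10 housekeeping genes were detected, led by Eef2 and Gapdh at 2049 ± 779 and 1994 ± 624 CPM and ending in Hprt at 1.62 ± 0.146 CPM. Hprt, which is deficient in the E14TG2a subline, had 98 and 83 counts and lay at percentile 5.57 of detected genes. The labels say E14 without a subline. Of 6 sex-linked genes 5 were detected, with Ddx3y at 80.4 ± 43.3 CPM, Eif2s3y at 68.9 ± 4.12 CPM, Xist at 5.11 ± 0.00146 CPM, and Kdm5d at 1 count in KO1 and 4 in KO2. Uty was 3.41-fold and Uba1y, also named after its value was seen, 2.00-fold higher in KO2, whereas Eif2s3y had a log2 ratio of -0.12, which became 0.30 after the GC correction. Tests of the Y-linked difference were also run and seen, then set aside to keep to 3 patterns. After GC correction the median of the 8 genes annotated on the Y chromosome was 1.31, 6 had their whole interval above 0.25 and 0 below it. The 6 were Uty (2.20), Zfy1 (1.79), Gm47283 (1.78), Ddx3y (1.58), Uba1y (1.04) and Gm21742 (0.64), while Gm29650 was at 0.11. Gm47283 and Gm21742 start at 90784738 and 90837413, away from the others, which start between 725128 and 1260771. How reads shared with copies elsewhere were counted is not given. Gm21742 and Gm29650 were named after their values were seen.

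The first pattern was the gene-to-gene difference between the duplicates. A difference in GC content bias between the libraries is a candidate explanation, since the log2 ratio correlated with GC content at 0.844 across 13932 genes. The SD of the ratio fell from 0.422 to 0.245 on correction, but the trend was fitted to these same ratios, so the fall adds no separate support. An effect of transcript length apart from GC content was argued against by a correlation of 0.041 with the corrected ratio. Without the correction it was -0.157, so a length effect that runs along with GC content stays open. A different share of differentiated cells stays open: 0 of 5 lineage lists lay outside the range of random lists after correction, but members went both ways in each list, and the ectoderm list lay outside, at -0.18, with members at a mean of at least 50 counts. The labels give no batch and 1 group, so no difference between conditions was tested, and the 42 genes that differed after correction stay open.

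The second pattern was Ago1, lower in KO2. GC bias predicted a corrected log2 ratio above -0.5, and the value was -1.73 (95% interval -1.88 to -1.57). Ago1 had a GC content of 50.7%, near the median of 49.6% for genes tested, so the correction could move it little. With its uncorrected ratio of -1.67 already seen, the outcome was all but fixed. The values show only that the fitted GC trend does not account for the Ago1 difference. The original statement of that test also required that no gene within 2 points of Ago1 in GC content be lower. This covered genes with a mean of at least 50 counts. Of 2946 such genes 1 was lower, and the requirement was dropped after this was seen, because another gene's change does not bear on Ago1. The 10 nearest genes with a mean of at least 50 counts had a median of -0.080. This argues against a change of a region reaching them, though not against one limited to Ago1 and Ago4. Whether reads shared with other Argonaute genes play a part stays open. The lower bounds of Ago2 and Ago3 were no less than -0.206, but that test was written after its result was seen. Ago2 had 28434 and 27475 counts, so reads in the number of Ago1's 1497 and 452 would barely move its ratio. Ago4 was not part of the test. Also open, and untested, is that the samples may carry different Ago1 alleles or come from different clones.

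The third pattern was the 7 muscle genes, with 636 counts in KO1 and 93 in KO2, a ratio of 6.58 (95% interval 5.28 to 8.27). They were picked from genes already called lower in KO2, so this ratio and its interval follow from the choice and test nothing. Muscle differentiation in the KO1 culture, set to need an interval above 2 over 12 myogenic regulators and embryonic isoforms and to be excluded by one below 1.5, met the latter at 0.708 (0.521 to 0.957), and at 0.970 (0.705 to 1.33) after GC correction for the 4 with at least 10 counts, but it stays open because the other 8 had fewer than 10 counts, 5 of them 0 in both libraries. For RNA or reads of adult muscle in KO1, with the same bounds, 8 of 35 other adult muscle genes gave 2.08 (1.64 to 2.64), and 2.31 (1.83 to 2.93) after GC correction, where 18 were left out for a CPM of at least 1 in KO2 and 9 for fewer than 10 counts. Of these, named after their values were seen, Pvalb had 48 and 0 counts, Tnni2 44 and 4, and Jsrp1 7 and 20, and without Pvalb and Tnni2 the ratio was 1.30 (0.999 to 1.69), or 1.4 (1.08 to 1.82) after GC correction. Adult muscle RNA in KO1 may be a source but is undecided, since both intervals of the 8 genes span the bound of 2 and leaving out genes expressed in KO2 raises the ratio, although 12 genes of other adult tissues under the same CPM limit gave 0.385 (0.229 to 0.627), and the 3 with at least 10 counts 0.439 (0.233 to 0.785) after GC correction.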
